A study of Mus musculus with 2 samples.

How the data were processed

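Single-cell RNA sequencing libraries had been made from tdTomato-positive spinal cord cells of Cx3cr1-CreER::Rosa26-tdTomato mice on the C57BL/6J background. In these mice 4-hydroxytamoxifen switches on the red fluorescent protein tdTomato permanently in cells that express the fractalkine receptor gene Cx3cr1, chiefly microglia and other resident macrophages. Circulating monocytes also express Cx3cr1, but are replaced from unlabelled precursors within weeks. Per the labels' protocols, each mouse received 2 injections of 1 mg of 4-hydroxytamoxifen at postnatal week 4, and cords were taken 4 weeks later, digested with collagenase at 2 mg/ml for 1 h at 37 °C and sorted for tdTomato in 1% bovine serum albumin. Scatter gates removed debris and cell doublets. cDNA was amplified over 10 cycles with the 10x Chromium 3′ version 2 chemistry, which captures polyadenylated RNA and tags each molecule with a unique molecular identifier (UMI). There were 2 libraries, 1 from uninjured age-matched cord and 1 from cord taken 5 days after an injection of lysolecithin, a detergent-like lipid that strips myelin from axons. The labels do not state how many animals, or of which sex, were pooled in either library.

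The deposited values are whole-number UMI counts per gene and barcode for 27998 genes. Per the submitters' processing notes, STAR, Cell Ranger 2.0.1, Seurat 2.1.0 and the mouse genome build GRCm38.p5 (mm10) were used. How each tool was applied, the gene annotation and any filter on barcodes are not given in the sources used here. The labels state 2500 sorted cells per library, with 705 cells recovered from uninjured and 580 from injured cord, and the matrices held 705 and 580 barcodes. Barcodes with at least 200 genes and at most 10% of UMIs from mitochondrial genes were kept. The gene minimum removed 0 barcodes, and the mitochondrial limit removed 10 uninjured and 3 injured barcodes, leaving 695 and 577. The kept cells held 2093084 UMIs in the uninjured and 3095511 in the injured library. Clec7a, fixed as a gene of interest, was not analysed here. Counts of the tdTomato transgene were likewise not analysed here, nor were those of Itgam, which stood under 2 identifiers.

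UMIs were summed over the kept cells of each library and scaled to CPM, which divides the UMIs of a gene by all UMIs of the library. A gene was measured with at least 20 UMIs over both libraries. Each ratio, injured over uninjured, was given on the log2 scale with the exact 95% interval of a ratio of 2 Poisson counts, computed as a Clopper-Pearson interval of the injured share of the gene's UMIs. A gene with 0 UMIs in a library was set to a floor of 3 counts there, which is 1.43 CPM in the uninjured and 0.969 CPM in the injured library, and its ratio is a lower bound (0 uninjured UMIs) or an upper bound (0 injured UMIs). Shares of cells have exact Clopper-Pearson 95% intervals and CPM values exact Poisson 95% intervals. All these intervals cover counting error only. With 1 library per group no difference has a replicate check, so no p-value, standard error or number of significant genes was computed, and the comparisons are between these 2 libraries.

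The genes named in the text follow a rule. Among genes with at least 50 UMIs in 1 library, ranked by the bound of the 95% interval nearest 0, the 12 highest and 12 lowest were taken, leaving out mitochondrial, ribosomal protein, haemoglobin, Rik and numbered Gm genes. Up to 4 members with the largest ratio were taken from each gene list, and 16 genes were fixed in addition. Values of some genes that the rule covers are not reported here. The same ranking gave 10 genes each way within clusters, and the 3 leading genes describe a cluster. There were 18 gene lists: homeostatic microglia, damage-associated microglia, cholesterol efflux and lipid handling, cholesterol synthesis, S phase, G2 and M phase, type I interferon response, cytokines and chemokines, MHC class I, MHC class II and costimulation, lysosome, glycolysis and hypoxia, oxidative phosphorylation, complement and phagocytic receptors, growth factors and matrix, dissociation-associated early response, oxidative stress and iron, and sex-linked genes. Some genes stand in several lists, among them Spp1, Gpnmb and Igf1 in damage-associated microglia and in growth factors and matrix. For each list the median log2 ratio of its measured members was given, with a counting interval from 500 Poisson draws, the number of members at least 2-fold higher or lower, and the percentile of the median among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these libraries only. Marker lists of 17 cell types were summed per library.

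For shares of cells with a UMI, each cell was thinned at random to 1500 UMIs without replacement, and cells below that depth were left out (91 uninjured and 10 injured). Cells of both libraries were clustered together on log-normalised counts (10000 per cell), the 2000 most variable genes, 20 principal components and a shared-neighbour graph of 20 neighbours, with the Leiden method at resolution 0.6. Clusters were named only from the fixed markers. The microglia-like class planned for a separate comparison failed its marker check: in clusters 3 and 5, which are 2 of the 7 clusters not called macrophage-like, markers of another class outnumbered those of microglia among the 10 leading genes. The same check failed at resolutions of 0.3 and 1.0 and without the list genes, and was not made for the clusterings under other cell filters or without Scrublet calls. Clusters were therefore compared by number, where both libraries had at least 30 cells. After the data were examined, barcodes with at least 5 UMIs of the endothelial or oligodendrocyte precursor markers were set apart, as a measure of free RNA in cells that should lack macrophage transcripts. Doublets were called with Scrublet as implemented in scanpy and kept in the comparisons. It called 11 of 695 uninjured barcodes (1.58%) and 2 of 577 injured ones (0.347%). None of the 17 injured barcodes with both Xist and Y-linked UMIs was among them.

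Gene coordinates were looked up by Ensembl identifier in the GENCODE M21 annotation of GRCm38, which held 9056 of the 9066 measured genes. The sequencing was of 3′ ends, and genes with near-identical copies may have shared UMIs: the Ifi200 family (Mnda, Ifi205, Ifi204), Ifit3 with Ifit3b, the H2 genes, Hspa1a with Hspa1b, and Xist with its antisense partner Tsix.

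Before the data were examined, the lists, markers, naming rule and most alternatives were fixed. These alternatives were edgeR TMM factors, DESeq2 size factors, scaling without mitochondrial and ribosomal protein genes, the mean over cells of each cell's CPM, no gene minimum or 100 UMIs, no cell filter or at least 500 genes and at most 5% mitochondrial UMIs, removal of Scrublet calls, thinning of every cell, Leiden resolutions of 0.3 and 1.0, clustering without the list genes, and thinning to 1000 or 2000 UMIs or not at all. Comparisons restricted to cells with Y-linked but no Xist UMIs, or without the macrophage-like cluster, or without cluster 7, or without the endothelial and oligodendrocyte precursor marker barcodes, were chosen after seeing the data. TMM and DESeq2 factors served as scalings alone, and neither package's test was run.

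The ratio and list calculations were tested on simulated Poisson counts for this comparison, with 200 of 9063 genes altered 2-, 4- or 8-fold either way. The intervals assume the same Poisson model, so this checks the calculation and not variation between cells or animals. Over 20 simulated pairs the 95% intervals held the true ratio for 94.7% to 96.1% of genes per fold size. In a separate single pair all 200 had the right sign, and the intervals held the true ratio for 79.4% (4-fold higher) to 100% (4-fold lower) of genes. Of genes with at least 50 UMIs, 19 of 34 set 2-fold higher and 11 of 27 set 2-fold lower came out at 2-fold or more, as did all of those set at 4- or 8-fold. A thinned share expected at 77.7% came out at 77.6% (95% interval 75.1 to 80.0%). Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.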

Results

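Messenger RNA was counted in single tdTomato-positive cells of mouse spinal cord, sorted from 1 preparation of uninjured cord and 1 preparation taken 5 days after lysolecithin injury. The uninjured library held 695 cells after filtering, with a median of 3003 UMIs (quartiles 2118 and 3775) and 1277 genes per cell. The injured library held 577 cells, with a median of 4396 UMIs (quartiles 3253 and 7033) and 1562 genes. In total 2093084 UMIs of 13239 genes were counted in uninjured and 3095511 UMIs of 14040 genes in injured cells. Mitochondrial genes took 2.05% and 2.59% of UMIs and ribosomal protein genes 12.8% and 14.4%. The gene with most UMIs was Cst3 (7.44%) in the uninjured library and Apoe (3.12%) in the injured one. With 1 library per group, all values describe these 2 libraries.

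The comparison of injured with uninjured cells addressed how cells of the Cx3cr1 lineage differ during demyelination. Spp1, which encodes the secreted phosphoprotein osteopontin, was 143-fold higher in the injured library, at 12396 CPM against 86.5 CPM (log2 7.16, 95% interval 6.95 to 7.38), and its log2 ratio was 6.36 in cells with Y-linked UMIs alone. Apoe, the main lipid carrier of the central nervous system, was 7.46-fold higher (log2 2.90, 2.87 to 2.93), and Lpl, a lipase that frees fatty acids from lipoproteins, had a log2 ratio of 3.17 (2.89 to 3.46). Cst3, the cysteine protease inhibitor cystatin C, was 4.25-fold lower (log2 −2.09, −2.10 to −2.07). The purinergic receptor gene P2ry12, used as a marker of resting microglia, was 3.93-fold lower (log2 −1.98, −2.04 to −1.91). Genes of damage-associated microglia, cell division and the interferon response stood higher as groups, and genes of homeostatic microglia stood lower.

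In GRCm38, Spp1 (ENSMUSG00000029304) lies on chromosome 5 at 104435118 to 104441050, Apoe (ENSMUSG00000002985) on chromosome 7 at 19696109 to 19699188, and Cst3 (ENSMUSG00000027447) on chromosome 2 at 148871722 to 148875692. P2ry12 (ENSMUSG00000036353) lies on chromosome 3 at 59216272 to 59262871, Tmem119 (ENSMUSG00000054675) on chromosome 5 at 113793729 to 113800516, and Gpnmb (ENSMUSG00000029816) on chromosome 6 at 49036546 to 49070929. All 6 are annotated as protein-coding.

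By size alone, 349 of the 5351 genes with at least 50 UMIs in 1 library were at least 2-fold higher in the injured cells and 456 at least 2-fold lower. The split moved with the scaling, to 432 higher and 325 lower with TMM factors and to 460 and 297 with DESeq2 size factors. These factors shifted every log2 ratio by 0.15 and 0.19. As reported, the median log2 ratio was −0.15 over all 9066 measured genes and −0.06 over the 5351.

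Sex-linked transcripts also differed between the libraries. Xist, the RNA that silences an X chromosome in female cells, had 8 UMIs in the uninjured and 958 in the injured library (log2 6.34, 5.36 to 7.56). The Y-linked genes Eif2s3y and Ddx3y had log2 ratios of −1.09 (−1.45 to −0.73) and −0.42 (−0.80 to −0.03), and the median of the 6 sex-linked genes was −0.49 (percentile 13.89 among random lists, 2 at least 2-fold higher and 1 lower). In the uninjured library 235 cells had Y-linked UMIs alone and 6 had Xist UMIs alone, against 147 and 213 in the injured library. The remaining cells had both (2 uninjured, 17 injured) or neither (452 and 200). List medians restricted to cells with Y-linked UMIs alone are given beside the groups that follow, as a comparison chosen after seeing the data.

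**Figure D1:**
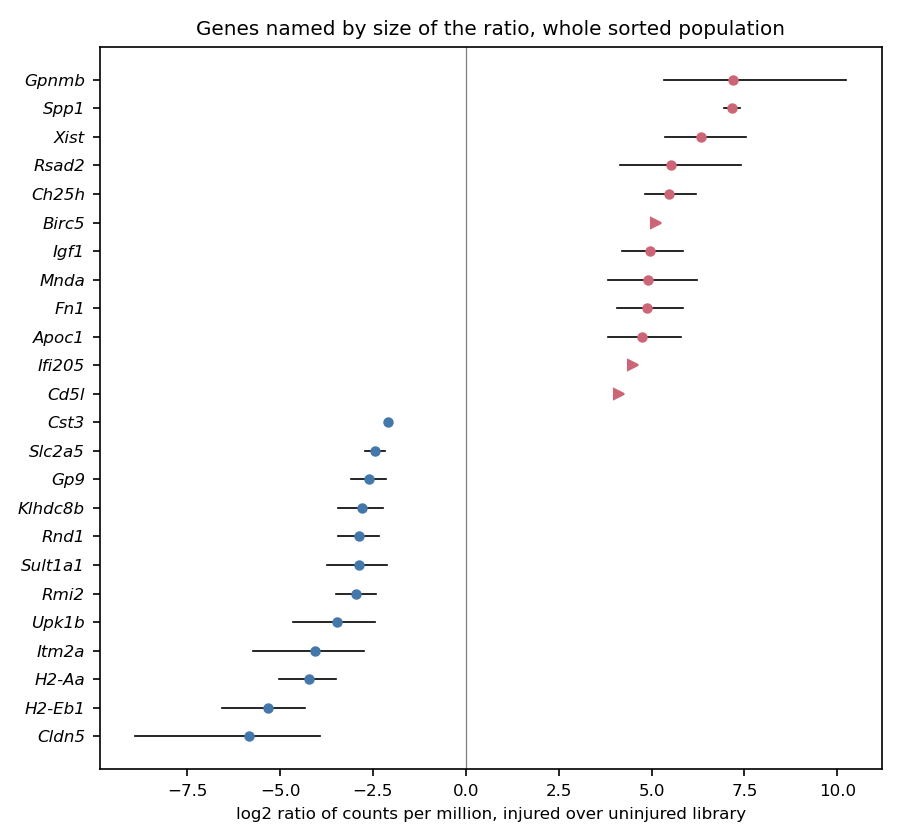
Log2 ratio of summed UMI counts, injured over uninjured, for the 12 highest and 12 lowest genes by the naming rule. Lines are 95% intervals of the ratio of 2 Poisson counts, and triangles mark lower bounds for genes with 0 uninjured UMIs (Birc5, Ifi205 and Cd5l); Spp1 stands at 7.16 and H2-Eb1 at −5.33.

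Among the 12 highest genes beside Spp1 and Xist were Gpnmb, a glycoprotein of phagocytic cells, with 2 uninjured and 434 injured UMIs (log2 7.20, 5.34 to 10.25), and Ch25h, which makes 25-hydroxycholesterol (log2 5.46, 4.81 to 6.20). Igf1, a growth factor for oligodendrocyte precursors, had a log2 ratio of 4.97 (4.21 to 5.85). All of its 14 uninjured UMIs came from 3 cells of the macrophage-like cluster 8, and without that cluster its log2 ratio was at least 7.17, from 0 uninjured UMIs. Fn1, the matrix protein fibronectin, was at 4.88 (4.06 to 5.84), the apolipoprotein gene Apoc1 at 4.74 (3.84 to 5.81), the interferon-induced antiviral gene Rsad2 at 5.53 (4.16 to 7.41) and Mnda of the Ifi200 family at 4.90 (3.84 to 6.23). Cluster 8 gave 6 of 10 uninjured Apoc1 and 4 of 7 uninjured Mnda UMIs, and without it these genes were at 6.05 and 6.09. The 32 cells of cluster 7 held 207 of the 309 injured Mnda UMIs, and without that cluster Mnda was at 3.39 and Rsad2 at 2.44. With 0 uninjured UMIs, the mitosis gene Birc5 was at least 34.5-fold, Ifi205 at least 22.8-fold and the macrophage survival gene Cd5l at least 17.4-fold higher. Cluster 7 also held 91 of the 101 injured Ifi205 UMIs.

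The 12 lowest genes had several sources. H2-Eb1 (log2 −5.33, −6.56 to −4.33) and H2-Aa (log2 −4.22, −5.02 to −3.51) encode chains of MHC class II, which presents peptides to T cells. Of their 218 and 214 uninjured UMIs, 201 and 199 came from the 9 uninjured cells of cluster 8. The tight junction gene Cldn5 (log2 −5.83, −8.90 to −3.93, with 2 injured UMIs) and Itm2a (log2 −4.05, −5.73 to −2.74) are endothelial markers, and 74 of 77 and 55 of 56 uninjured UMIs lay in cluster 5. The microglial fructose transporter gene Slc2a5 (log2 −2.44, −2.71 to −2.17), Gp9 (−2.61, −3.09 to −2.15), Upk1b (−3.46, −4.65 to −2.45) and Sult1a1 (−2.89, −3.73 to −2.12) were also lower. So were Rnd1 (−2.87, −3.44 to −2.34), Klhdc8b (−2.80, −3.44 to −2.22) and Rmi2 (−2.95, −3.51 to −2.43), the last with 70.7% of its uninjured UMIs in 10 cells.

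Of 23 measured damage-associated genes, first described in microglia around amyloid plaques, 15 were at least 2-fold higher and 0 lower in the injured library. Their median log2 ratio was 2.09 (counting interval 1.74 to 2.26), above all 10000 random lists. The list includes Spp1, Gpnmb, Ch25h and Igf1, the cystatin gene Cst7 (3.27, 2.97 to 3.59), and Itgax, for which 8 and 23 UMIs gave a ratio not distinguishable from 0 (0.96, −0.25 to 2.33). Of 20 homeostatic genes, 11 were at least 2-fold lower and 0 higher, with a median of −1.17 (−1.27 to −1.03) that lay below all random lists. Besides P2ry12 and Cst3, the lens crystallin gene Crybb1 (−2.28, −2.51 to −2.06), the adhesion receptor gene Adgrg1 (−2.31, −2.58 to −2.05) and the microglial marker Tmem119 (−1.60, −1.68 to −1.53) were lower. Cx3cr1, the gene that drives the lineage label, was 1.79-fold lower (−0.84, −0.96 to −0.73). Among cells with Y-linked UMIs alone the medians were 1.90 and −0.99.

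Genes that move lipid out of cells or store it were higher as a group. The cholesterol efflux and lipid handling list had a median of 2.096 (1.64 to 2.37; percentile 100), with 10 of 18 members at least 2-fold higher and 0 lower. The median was 1.30 with no gene minimum and 1.59 without the endothelial and oligodendrocyte precursor marker barcodes. Its members shared with the damage-associated list include Apoe, Lpl and Ch25h. The lipid droplet coat gene Plin2 was at 3.86 (3.51 to 4.23). Fabp4 was at 4.02 (2.42 to 6.33), with its 72 injured UMIs in 5 cells and 69 of them in 2 cells of cluster 5. The cholesterol synthesis list, with a median of −0.51 (−0.87 to −0.24; percentile 8.62), stayed within the middle 95% of random lists, with 4 of 15 members at least 2-fold lower and 0 higher. Insig1, which holds back sterol synthesis, was at −1.32 (−1.61 to −1.04), and the sterol enzymes Sc5d, Msmo1 and Cyp51 were at −1.13 (−1.62 to −0.65), −0.82 (−1.17 to −0.47) and −0.51 (−1.06 to 0.04). With every cell thinned Insig1 was at −0.82 and Sc5d at −0.43, and Sc5d was also below the 2-fold size with TMM factors (−0.99), DESeq2 size factors (−0.95) and per-cell means (−0.88). Among cells with Y-linked UMIs alone these medians were 2.57 and −0.92.

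Cell cycle genes were higher in the injured library. Of 20 measured genes of the G2 and M phases, 18 were at least 2-fold higher and 0 lower, with a median of 3.01 (2.73 to 3.92; percentile 100). Ccnb2 and Pbk each had 1 uninjured UMI, with log2 ratios of 6.06 (3.55 to 11.38) and 5.66 (3.14 to 10.99). Top2a, the topoisomerase that untangles replicated DNA, was at 4.08 (2.48 to 6.39) from 3 and 75 UMIs, and the proliferation marker Mki67 at 2.76 (1.07 to 5.11) from 3 and 30. Of 18 S phase genes, 10 were at least 2-fold higher and 0 lower (median 1.40, 0.92 to 1.80; percentile 100). The ribonucleotide reductase genes Rrm2 and Rrm1 were at 2.99 (1.88 to 4.34) and 1.87 (0.88 to 3.01), and the replication helicase genes Mcm6 and Mcm4 at 2.34 (1.53 to 3.26) and 1.91 (0.87 to 3.12). With a minimum of 100 UMIs the S phase median was 0.14. Among cells with Y-linked UMIs alone the medians were 2.20 for G2 and M phase and 0.55 for S phase.

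The type I interferon response list was higher for 19 of its 20 members at the 2-fold size, with 0 lower and a median of 2.78 (2.65 to 3.16; percentile 100). Besides Rsad2, the nucleic acid sensor gene Zbp1 was at 3.85 (2.94 to 4.93), Ifit1 at 3.80 (2.94 to 4.83), Ifit3 at 3.31 (2.82 to 3.84; 2.13 with Y-linked UMIs alone) and Ifi27l2a at 3.61 (3.38 to 3.84). A few cells held much of this signal: the 10 injured cells with most UMIs of each gene held 49.7% of Ifit3 and 65.9% of Rsad2 UMIs. Without the 32 cells of cluster 7, a comparison chosen after seeing the data, the median was 1.93, with 16 of 19 members at least 2-fold higher, and Rsad2 was at 2.44, Ifit1 at 1.93 and Ifit3 at 1.19. The median among cells with Y-linked UMIs alone was 2.34. Of 22 cytokine and chemokine genes, 12 were at least 2-fold higher and 2 lower (median 1.04, 0.96 to 1.15; percentile 100; 0.91 with Y-linked UMIs alone). Higher were Cxcl14 (4.29, 2.70 to 6.599), Il1rn, the antagonist of the interleukin-1 receptor (4.06, 3.26 to 4.98), and the chemoattractant genes Ccl5 (3.72, 3.37 to 4.10) and Ccl7 (2.63, 2.22 to 3.06). The 10 cells with most UMIs in each library held 76.1% of uninjured and 63.9% of injured Ccl5 UMIs, and 75.9% and 58.8% of Ccl7 UMIs. Cluster 8 gave 2 of 3 uninjured Cxcl14 UMIs, and without it Cxcl14 was at 5.85. Ccl4 differed less, at 0.55 (0.51 to 0.59).

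MHC class I genes, which present peptides from inside the cell, had a median of 0.27 (0.21 to 0.39; percentile 89.13), within the middle 95% of random lists, with 1 of 10 members at least 2-fold higher and 0 lower. H2-Q7 was at 1.82 (1.24 to 2.44), the peptide transporter genes Tap1 and Tap2 at 0.69 (0.23 to 1.17) and −0.65 (−0.95 to −0.35), and B2m at 0.50 (0.47 to 0.54). MHC class II and costimulation genes had a median of −0.60 (−0.96 to −0.50; percentile 0.84) and of −0.46 without cluster 8, with 4 of 10 at least 2-fold lower and 1, Cd40 (1.89, 0.91 to 3.03), at least 2-fold higher. H2-Ab1 was at −2.29 (−2.61 to −1.99) and the invariant chain gene Cd74 at −1.37 (−1.48 to −1.26). These ratios rested on the macrophage-like cluster 8: without its cells H2-Ab1 was at −0.03, H2-Aa at −0.66, H2-Eb1 at −2.33 and Cd74 at 0.32. The medians with Y-linked UMIs alone were 0.28 and −0.56.

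Metabolic and lysosomal genes were moderately higher. The glycolysis and hypoxia list had a median of 0.96 (0.87 to 1.17; percentile 100), with 9 of 19 members at least 2-fold higher and 2 lower. The glycolytic enzyme genes Pgk1 and Pgam1 were at 3.07 (2.41 to 3.80) and 1.76 (1.56 to 1.97), the lactate exporter gene Slc16a3 at 1.78 (1.45 to 2.14) and the hypoxia regulator gene Hif1a at 1.46 (1.13 to 1.81). Oxidative phosphorylation genes had a median of 0.45 (0.37 to 0.53; percentile 98.87), with 1 of 16, Cox5a (1.16, 0.95 to 1.38), at least 2-fold higher and 0 lower; Uqcrq, Cox4i1 and Atp5e were at 0.89 (0.72 to 1.05), 0.66 (0.57 to 0.75) and 0.66 (0.53 to 0.79). Of 29 lysosome genes 5 were at least 2-fold higher and 0 lower (median 0.36, 0.31 to 0.45; percentile 99.28), among them Cd63 (2.09, 1.99 to 2.18), the protease gene Ctsb (1.62, 1.58 to 1.66) and Gusb (1.19, 1.06 to 1.33; 0.94 with every cell thinned). Of 11 oxidative stress and iron genes 4 were at least 2-fold higher and 0 lower (median 0.68, 0.52 to 0.99; percentile 99.92). The cystine importer gene Slc7a11 was at 3.76 (2.74 to 4.99), Mt2 at 1.45 (1.04 to 1.89), Prdx1 at 1.05 (0.95 to 1.14; 0.86 with every cell thinned) and Txnrd1 at 0.82 (0.46 to 1.19). With Y-linked UMIs alone the medians of these lists were 1.12, 0.51, 0.38 and 0.58.

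The complement and phagocytic receptor list stood near the middle of the random lists, with a median of −0.10 (−0.14 to 0.19; percentile 23.08) that was 0.04 with TMM factors, 0.08 with DESeq2 size factors and −0.01 with Y-linked UMIs alone. Of its 23 members 4 were at least 2-fold higher and 0 lower. Among these were the scavenger receptor genes Msr1 (3.89, 2.94 to 5.04) and Cd36 (2.61, 1.61 to 3.79) and the phagocytic receptor kinase gene Axl (1.92, 1.48 to 2.39), while C5ar1 was at 0.89 (0.76 to 1.03). With every cell thinned Axl was at 2.84. Of 9 uninjured UMIs each, 6 for Msr1 and 7 for Cd36 came from cluster 8, and without it their log2 ratios were 5.38 and 4.65. Of 17 growth factor and matrix genes 8 were at least 2-fold higher and 2 lower (median 0.46, 0.34 to 1.02; percentile 99.7; 1.08 with Y-linked UMIs alone), led by Gpnmb, Spp1, Igf1 and Fn1. The dissociation-associated early response, which is induced when tissue is digested while warm, was lower in the injured library for 9 of 25 members at the 2-fold size and higher for 0. Its median was −0.87 (−0.96 to −0.71), below all random lists, and the same value was reached with Y-linked UMIs alone (−0.87). Jun was at −2.05 (−2.14 to −1.96), Hspa1a at −1.74 (−1.81 to −1.66), Dusp1 at −1.502 (−1.68 to −1.32) and Btg2 at −1.39 (−1.51 to −1.28).

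**Figure D2:**
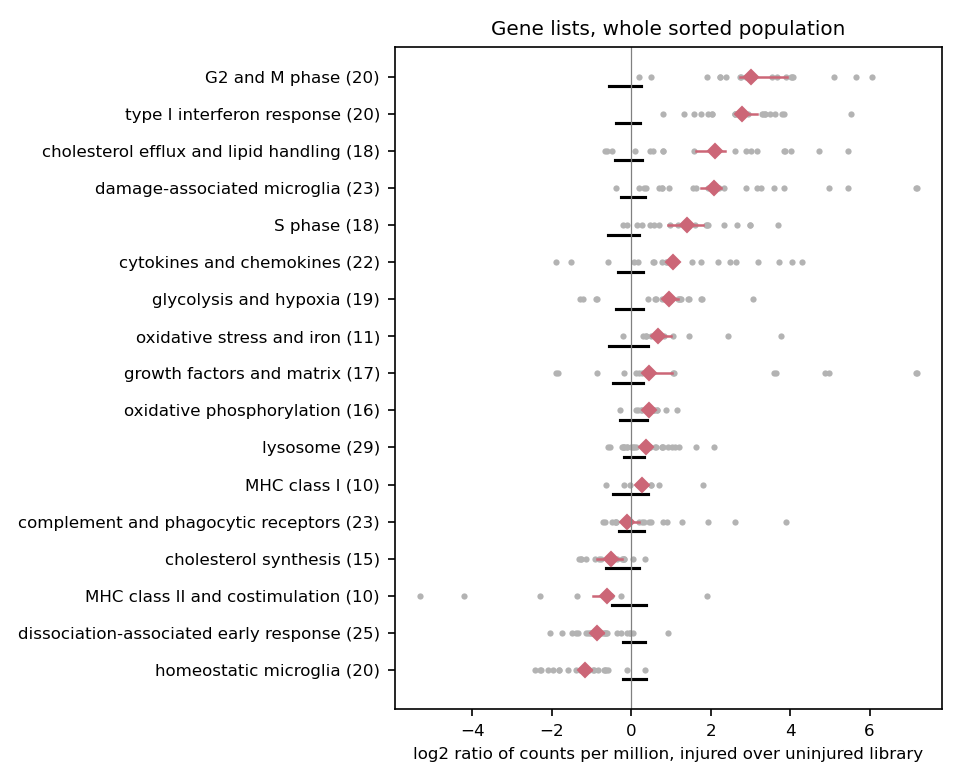
Log2 ratio, injured over uninjured, of the members of each gene list (grey dots; number measured in brackets), with the list median (diamond), its counting interval (red line) and the range that holds the middle 95% of random-list medians (black bars). G2 and M phase genes had a median of 3.01 and homeostatic microglia genes one of −1.17.

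Shares of cells with a UMI were compared after thinning each cell to 1500 UMIs, in 604 uninjured and 567 injured cells. P2ry12 was seen in 96.2% (94.3 to 97.6%) of uninjured and 63.0% (58.8 to 66.9%) of injured cells, Tmem119 in 92.5% (90.2 to 94.5%) and 61.2% (57.1 to 65.2%), and Cx3cr1 in 59.6% (55.6 to 63.5%) and 37.2% (33.2 to 41.3%). Apoe was seen in 57.8% (53.7 to 61.8%) and 98.1% (96.6 to 99.0%), and Spp1 in 3.64% (2.30 to 5.46%) and 76.2% (72.5 to 79.6%). Lpl was seen in 3.97% (2.56 to 5.85%) and 24.5% (21.0 to 28.3%), Cst7 in 3.64% (2.30 to 5.46%) and 34.4% (30.5 to 38.5%), Ifit3 in 1.99% (1.03 to 3.44%) and 9.35% (7.08 to 12.05%), and Ccl4 in 63.4% (59.4 to 67.3%) and 80.1% (76.5 to 83.3%). Without thinning, the shares were 97.6% and 85.8% for P2ry12, 94.96% and 86.5% for Tmem119, 77.7% and 73.3% for Cx3cr1, and 70.1% and 100% for Apoe. They were 6.04% and 91.0% for Spp1, 7.05% and 48.2% for Lpl, 5.61% and 54.4% for Cst7, 2.88% and 16.5% for Ifit3, and 70.5% and 89.6% for Ccl4.

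Free RNA set a background for some of these shares. Of the barcodes with endothelial or oligodendrocyte precursor markers, 4 were uninjured (median 1737 UMIs) and 7 injured (median 3262 UMIs). An Apoe UMI was present in 4 of 4 and 6 of 7 of them and a Spp1 UMI in 0 of 4 and 7 of 7. Cst7 was seen in 0 of 4 and 2 of 7, Ccl4 in 1 of 4 and 2 of 7, P2ry12 in 2 of 4 and 1 of 7, Tmem119 in 1 of 4 and 0 of 7, and Cx3cr1, Lpl and Ifit3 in 0 of 4 and 0 of 7. So few barcodes left wide intervals, and only the shares for P2ry12 and Tmem119 in both libraries and for Ccl4 in the injured one had lower limits above the upper limit of this background. The other shares, among them those for Apoe, Spp1 and Cst7, were not separated from it and give no order.

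Rare genes gave few cells. Itgax was seen in 0.828% (0.269 to 1.92%) of uninjured and 1.23% (0.498 to 2.53%) of injured cells, Mki67 in 0.331% (0.0401 to 1.19%) and 1.59% (0.728 to 2.99%), and Mrc1 in 0.828% (0.269 to 1.92%) and 0.529% (0.109 to 1.54%). For Ccr2, the chemokine receptor of blood monocytes, the shares were 0.166% (0.0042 to 0.919%) and 0.882% (0.287 to 2.05%), and its CPM did not differ detectably (log2 −0.03, −1.37 to 1.37). The log2 ratio of Mrc1 was −0.67 (−1.88 to 0.53). Top2a was seen in 0 of 604 uninjured cells, with an upper limit of 0.609% for detection at this depth, and in 1.94% (0.972 to 3.44%) of injured cells. Unthinned shares were 1.15% and 3.81% for Itgax, 0.288% and 3.47% for Mki67, 1.29% and 1.04% for Mrc1, 0.576% and 0.867% for Ccr2, and 0.432% and 5.37% for Top2a. Cd74 was seen in 21.7% (18.5 to 25.2%) of uninjured and 31.2% (27.4 to 35.2%) of injured cells, or 32.9% and 54.6% without thinning. Its CPM was lower in the injured library, and 1284 of its 1837 uninjured UMIs came from 9 cells of cluster 8. Its log2 ratio without that cluster was 0.32. The endothelial and oligodendrocyte precursor marker barcodes held a Cd74 UMI in 0 of 4 and 0 of 7 cases, too few to separate the shares from background, so these give no order.

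At least 2 UMIs of the G2 and M phase list were found in 13.6% (10.9 to 16.6%) of uninjured and 24.3% (20.9 to 28.1%) of injured cells after thinning, and in 30.5% and 58.2% without it. Without Hmgb2 and Cks2, genes also expressed outside division, the thinned shares were 0.331% (0.0401 to 1.19%) and 7.41% (5.39 to 9.88%). For the S phase list they were 16.4% (13.5 to 19.6%) and 18.7% (15.6 to 22.2%), or 40.7% and 54.9% without thinning, and the thinned intervals overlap. Such counts per cell also read free RNA, whose level in each library was not measured for these genes.

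**Figure D3:**
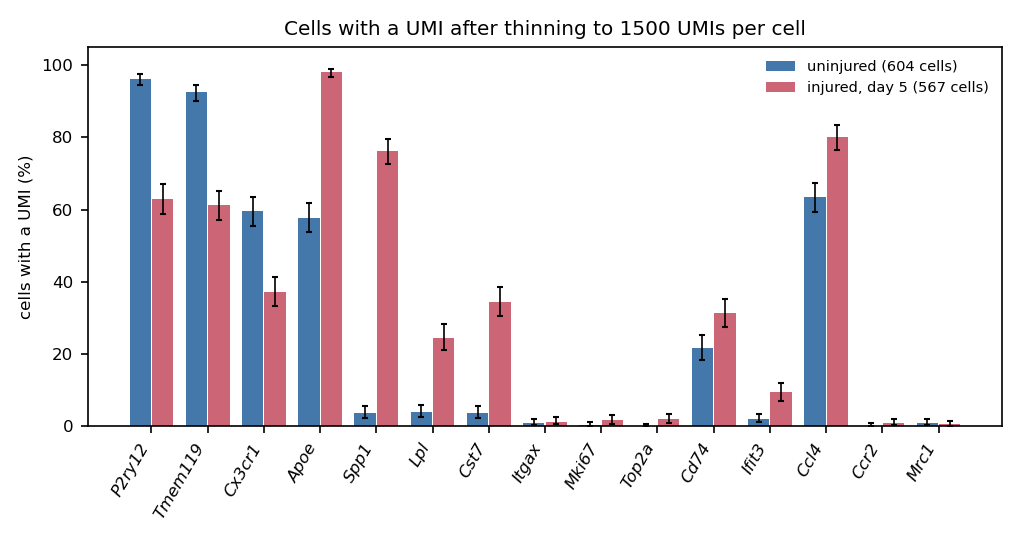
Percent of cells with a UMI of each fixed gene except Clec7a, after thinning to 1500 UMIs, in uninjured (604 cells) and injured (567 cells) libraries. Error bars are Clopper-Pearson 95% intervals; the P2ry12 share is 96.2% against 63.0%.

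Joint clustering gave 8 clusters, whose makeup by library describes these libraries and not cell types, since the genes that set them apart also differed between the libraries. Clusters 1 (324 uninjured and 30 injured cells; led by Ddit4, Hbegf and Gm12216), 2 (71 and 198; 4930548H24Rik, Tnfrsf12a and Rrad), 5 (103 and 35; Cldn5, Fabp4 and Itm2a) and 6 (39 and 68; Fabp7, Pllp and Gap43) held at least 30 cells of each library. Cluster 3 (3 and 199) was led by Igf1, Fn1 and Lpl, cluster 4 (146 and 2) by Emilin1, Il16 and Hist4h4, and cluster 7 (0 and 32) by Rsad2, Ifit3 and Ifit3b. Cluster 8, led by H2-Eb1, H2-Aa and H2-Ab1, carried Mrc1, Pf4, Ms4a7 and F13a1 and was called border-associated macrophage-like. Some leading genes were carried by few cells and do not describe their cluster: 4930548H24Rik was seen in 1 of 269 cells of cluster 2 and Emilin1 in 2 of 148 of cluster 4. Cldn5, Fabp4 and Itm2a were seen in 4, 2 and 5 of 138 cells of cluster 5, and Fabp7, Pllp and Gap43 in 8, 9 and 8 of 107 of cluster 6. Cluster 8 made up 9 of 695 uninjured cells (1.29%, 0.594 to 2.44%) and 13 of 577 injured cells (2.25%, 1.205 to 3.82%), shares whose intervals overlap. At resolution 0.3, or without the list genes, no such cluster was found.

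Within the 4 clusters with enough cells of both libraries, interferon genes were higher in injured cells, with medians of 1.00, 1.33, 1.08 and 2.01 in clusters 1, 2, 5 and 6. These rest on the 9, 16, 5 and 6 members measured there, whose medians in the whole population were 2.02, 2.61, 2.02 and 2.78. Damage-associated genes differed less within clusters, with medians of 0.23, 0.43, 0.44 and 1.15, the lowest of which was −0.0000032 with TMM factors and −0.0079 with a minimum of 100 UMIs per gene. For the 15, 19, 12 and 20 members measured there, the medians in the whole population were 1.56, 1.92, 0.78 and 2.00. The list genes were not left out of the clustering, which groups cells alike in them, so smaller ratios within clusters could be built in. Cluster 3, with 3 uninjured and 199 injured cells, was not compared. These medians therefore do not tell how much of the difference lies between clusters. Cholesterol efflux and lipid handling gave 0.33, 0.60, 0.57 and 1.24, and the lysosome list 0.08, 0.17, 0.26 and 0.75. Homeostatic medians were −0.29, −0.21, −0.54 and −1.11, with 1, 0, 5 and 10 members at least 2-fold lower. Early response medians were −0.21, −0.37, −0.42 and −0.19. The cluster 1 and 5 values rest on 30 and 35 injured cells. Those of cluster 6 rest on 39 uninjured cells with 69387 UMIs, against 278230 UMIs in 68 injured cells. Cst3 stood at 118596 CPM in these uninjured cells and at 74425 CPM in the whole uninjured library. Whether cluster 6 held the same kind of cells in both libraries was not tested.

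By the naming rule, Ifi27l2a, an interferon-induced gene, and Spp1 were among the 10 highest genes in all 4 clusters and Apoe in 3 of them. Cst3, the leukocyte adhesion ligand gene Selplg and the cytokine signal inhibitor gene Socs3 were among the 10 lowest in 3 clusters. Log2 ratios of Ifi27l2a were 2.84 (2.18 to 3.50), 3.74 (2.96 to 4.66), 3.38 (2.46 to 4.42) and 3.47 (2.41 to 4.79) in clusters 1, 2, 5 and 6. Those of Apoe were 1.95 (1.84 to 2.06), 0.94 (0.87 to 1.01), 2.16 (2.03 to 2.30) and 2.85 (2.71 to 2.99). Spp1 was at 4.92 (4.15 to 5.75), 3.57 (3.01 to 4.19), 5.10 (4.01 to 6.45) and, from 1 uninjured UMI, 10.48 (8.005 to 15.79). In clusters 1 and 5 its injured levels without barcodes of other cell types, 555 and 803 CPM, lay inside the interval of the 7 injured endothelial and oligodendrocyte precursor marker barcodes (705 CPM, 424 to 1101). Cst3 was at −1.01 (−1.06 to −0.96), −0.83 (−0.86 to −0.80) and −2.51 (−2.55 to −2.46) in clusters 1, 2 and 6. P2ry12 was at −0.24 (−0.42 to −0.07), −0.49 (−0.64 to −0.33), −0.93 (−1.14 to −0.72) and −1.56 (−1.88 to −1.25), and Socs3 at −1.47 (−2.09 to −0.90), −1.05 (−1.39 to −0.71) and −2.31 (−3.05 to −1.65) in clusters 1, 2 and 5.

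**Figure D4:**
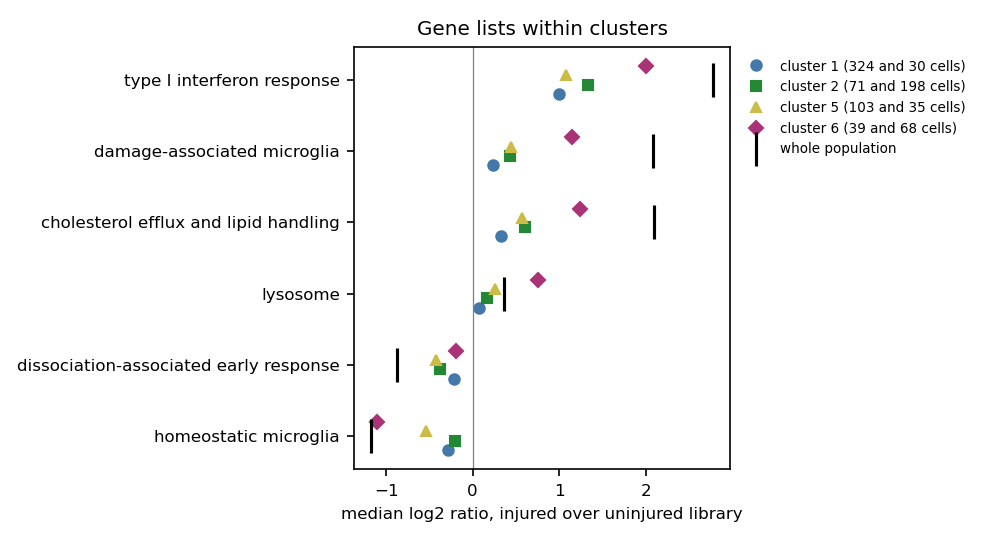
Median log2 ratio, injured over uninjured, in the 4 clusters with at least 30 cells of each library (numbers of uninjured and injured cells in brackets) and in the whole population (black ticks). The lists shown are homeostatic microglia, dissociation-associated early response, lysosome, cholesterol efflux and lipid handling, damage-associated microglia and type I interferon response. The damage-associated medians lie between 0.23 and 1.15 within clusters (the lowest at −0.0000032 with TMM factors and −0.0079 with a minimum of 100 UMIs), and clusters measure fewer members than the whole population.

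**Figure D5:**
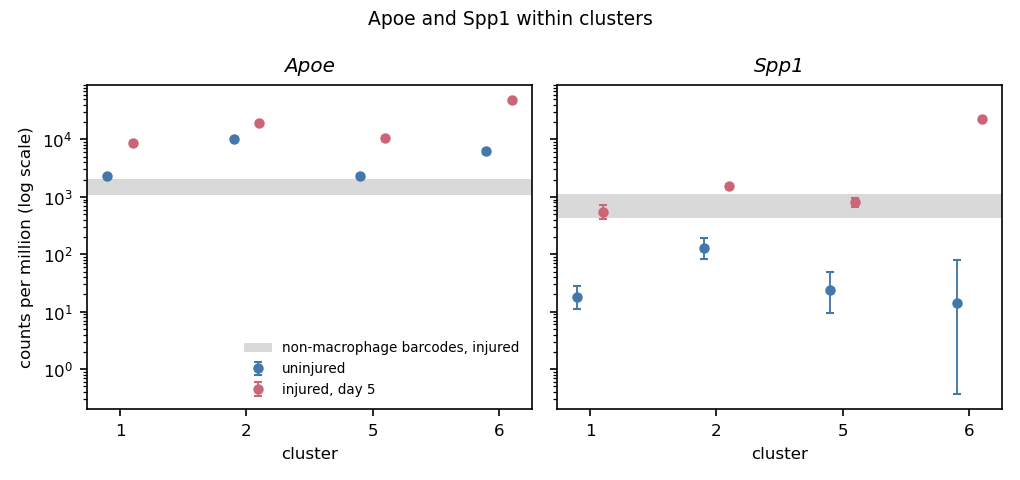
Apoe and Spp1 levels (CPM, log axis) in uninjured and injured cells by cluster, with Poisson 95% intervals. The grey band is the interval in the 7 injured barcodes with endothelial or oligodendrocyte precursor markers, 1092 to 2064 CPM for Apoe and 424 to 1101 CPM for Spp1.

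Markers of other cell types took small parts of both libraries. The microglia markers summed to 26966 CPM (26744 to 27189) in the uninjured and 16344 CPM (16202 to 16487) in the injured library, and the border-associated macrophage markers to 150.02 (134 to 168) and 197 CPM (181 to 213). Monocyte and monocyte-derived macrophage markers summed to 283 (261 to 307) and 671 CPM (642 to 700). Fn1 gave 12 of their 593 uninjured and 522 of their 2077 injured UMIs. Without thinning, at least 5 UMIs of these markers were found in 18 of 695 uninjured and 160 of 577 injured cells. For the border-associated macrophage markers the numbers were 8 and 31. Neutrophil markers summed to 204 (186 to 225) and 86.6 CPM (76.5 to 97.6), oligodendrocyte markers to 230.3 (210.2 to 252) and 125 CPM (113 to 138), endothelial markers to 114 (100.2 to 130) and 22.6 CPM (17.6 to 28.6), and astrocyte markers to 81.2 (69.5 to 94.4) and 42.0 CPM (35.1 to 49.9). Fibroblast markers summed to 42.0 (33.7 to 51.8) and 67.8 CPM (59.0 to 77.7), oligodendrocyte precursor markers to 0.956 (0.116 to 3.45) and 27.1 CPM (21.6 to 33.6), and B cell markers to 25.3 (19.0 to 33.1) and 12.6 CPM (8.96 to 17.2). Neuronal markers stood at 14.3 (9.67 to 20.5) and 8.72 CPM (5.75 to 12.7) and dendritic cell markers at 10.0 (6.21 to 15.3) and 3.55 CPM (1.77 to 6.36). Mural markers had 8 and 13 UMIs, erythroid markers 3 and 11, ependymal markers 1 and 5, Schwann cell markers 1 and 4, and T and NK cell markers 0 and 1.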

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

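The comparisons without the macrophage-like cluster, without cluster 7, without the endothelial and oligodendrocyte precursor marker barcodes and with Y-linked UMIs alone were chosen after seeing the data. Of 75 named genes at least 2-fold different with an interval off 0, all that were measured kept their direction in every setting run except Cd74 without the macrophage-like cluster (log2 0.32). Those still at 2-fold numbered 73 of 75 with TMM or DESeq2 factors, 69 of 75 with per-cell means, 66 of 71 with thinned cells and 62 of 64 with Y-linked UMIs alone. The 17 list medians rerun kept their direction in all 14 settings except complement and phagocytic receptors, at 0.0441 with TMM and 0.0818 with DESeq2 factors. The homeostatic median was −1.02 with TMM, −0.98 with DESeq2, −0.95 with per-cell means and −0.99 with Y-linked UMIs alone, and the damage-associated median 2.27 with DESeq2 and 2.32 with thinned cells. The lowest damage-associated median within a cluster was −0.0000032 with TMM and −0.0079 with a minimum of 100 UMIs. Genes at least 2-fold lower numbered 297 with DESeq2. With fewer UMIs, 152 were higher and 207 lower (thinned cells), and 173 and 235 (Y-linked UMIs alone). Under the stricter cell filter and under Leiden resolution 0.3, only 2 clusters held 30 cells of each library, and in these 2 the damage-associated median was above 0 and the homeostatic median below 0. G2 and M phase shares moved with depth, at 7.42% and 16.3% (1000 UMIs), 19.3% and 32.6% (2000) and 30.5% and 58.2% (no thinning). The cause of the other moves was not tested. The comparison within the microglia-like class was not run, as the class failed its marker check. No paired analysis was possible because each group has 1 library. Genes with few UMIs are limited by depth, as their intervals show.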

Other observations

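Tests chosen only after the result was seen were those of free RNA, doublets and the 10 microglia markers, the comparisons of dividing cells, of cluster 8 and of interferon genes by sex, and the limits of the depth test, while thinning itself had been fixed before. Injured cells with at least 5 G2 and M phase UMIs after thinning numbered 27 of 567, and 23 of them lay in cluster 3 (11.6% of its 199 injured cells, 7.47 to 16.8%). They were therefore compared with the other 176 injured cells of that cluster. Genes of lipid handling and of the damage-associated list were lower in the dividing cells of cluster 3. The 10 leading genes of that cluster include Igf1, Lpl, Spp1 and Gpnmb but also the mitosis gene Birc5. Cells could be grouped there by either set, so part of this difference may come from the clustering. Apoe stood at 15088 against 37173 CPM (log2 −1.30, −1.36 to −1.24), Spp1 was at −0.82 (−0.89 to −0.75), Igf1 at −1.60 (−2.32 to −0.95) and Gpnmb, from 3 UMIs, at −3.68 (−5.97 to −2.13). P2ry12 was higher than in other cells of cluster 3 (0.48, 0.11 to 0.84) but lower than in all 540 other injured cells (−0.73, −1.03 to −0.43), where Spp1 was at −0.23 (−0.30 to −0.17) and Apoe at −1.07 (−1.12 to −1.01). Within cluster 3 the damage-associated median was −0.69, the cholesterol efflux and lipid handling median −0.61 and the lysosome median −0.39 (percentile 0 among random lists for all 3), and the homeostatic median 0.13 (percentile 88.83), while 10 of 16 S phase genes were at least 2-fold higher. Against all other injured cells the homeostatic median turned to −0.32 (percentile 0.02), the damage-associated median was −0.30 (percentile 0.14) and the interferon median 0.66 (percentile 100). The interferon median within cluster 3 was 0.28 (percentile 93.59), inside the middle 95% of random lists, and 2 of the 4 dividing cells outside cluster 3 lay in the interferon-rich cluster 7.

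In the border-associated macrophage-like cluster, 9 uninjured and 13 injured cells differed in MHC class II genes. Cd74 stood at 37713 CPM (35678 to 39833) in uninjured and 587 CPM (399 to 833) in injured cells, and H2-Ab1 at 8870 (7898 to 9929) and 75.7 CPM (20.6 to 194). Spp1 stood at 323 (161 to 578) and 2895 CPM (2455 to 3392), Ms4a7 at 793 (523 to 1154) and 1609 CPM (1285 to 1989), and Pf4 at 1939 (1499 to 2466) and 643 CPM (446 to 899). The acute phase gene Saa3 had 208 uninjured UMIs, in 2 cells. Lyz1 stood at 352 (182 to 616) and 1060 CPM (801 to 1376). The monocyte gene Ccr2 was seen in 1 of 9 and 4 of 13 cells, at 176 (64.7 to 384) and 227 CPM (117 to 397). Whether the cluster held the same mix of cells in both libraries was not tested, so these differences need not lie within 1 cell type. Within the injured library, 213 cells with Xist UMIs alone had a higher interferon median than 147 cells with Y-linked UMIs alone (0.86, 0.74 to 1.09; percentile 100), with Rsad2 at 3.14 (2.35 to 4.04) and Ifit3 at 1.61 (1.24 to 2.00). Cytokine (0.48, 0.41 to 0.55; percentile 100), G2 and M phase (0.46, 0.31 to 0.86; percentile 99.97) and dissociation-associated early response (0.17, 0.09 to 0.23; percentile 100) medians were also higher in the Xist-only cells, as were those of glycolysis and hypoxia (0.20, 0.13 to 0.30; percentile 99.96) and MHC class II (0.27, 0.07 to 0.44; percentile 99.41). The growth factor and matrix median was −0.18, at percentile 0.74, but its counting interval (−0.33 to 0.04) included 0. The share of cells with at least 2 G2 and M phase UMIs did not differ detectably, at 58 of 210 Xist-only (21.7 to 34.2%) and 36 of 144 Y-only cells (18.2 to 32.9%) after thinning. Of the Xist-only and Y-only cells 19 (8.92%, 5.46 to 13.6%) and 6 (4.08%, 1.51 to 8.67%) lay in cluster 7, which held 33.2% of the injured library's interferon UMIs. Sex and animal are not separable here.

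Damage-associated genes were higher and homeostatic genes lower in the injured library. The presence of female cells was excluded as the whole cause, since within the injured library the damage-associated median of Xist-only over Y-only cells was −0.0048 (−0.05 to 0.03). The greater weight of deeper cells was excluded as the whole cause too, since the median was 2.32 with every cell thinned to 1500 UMIs and 1.92 with per-cell means. Thinning leaves each cell's expected CPM unchanged, so it could not test other effects of depth. A response to the injury may underlie the pattern, as a hypothesis, but differences between the preparations or animals stay open because each group has 1 library.

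Apoe and Spp1 were higher in injured cells of all 4 clusters compared. Free RNA was excluded as the whole cause for Apoe, whose smallest excess over uninjured cells was 6539 CPM (5965 to 7145) against an upper limit of 2064 CPM in the injured barcodes with endothelial or oligodendrocyte precursor markers. For Spp1 in clusters 2 and 6 it was also excluded, as the lower level, 1535 CPM (1447 to 1626), lay above the limit of 1101 CPM. In clusters 1 and 5 Spp1 reached at most 803 CPM, within the interval of those barcodes, so free RNA could account for it there. The comparison rests on 7 barcodes, and a biological difference in clusters 2 and 6 stays a hypothesis.

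Cluster 3 held 3 uninjured and 199 injured cells with a median of 7619 UMIs, and as a cluster of nearly 1 library it may be that library and not a cell type. Doublets were excluded for most of its cells: 5.96% (2.76 to 11.0%) of its sex-typed injured barcodes had both Xist and Y-linked UMIs, against 24.3% (23.4 to 25.3%) of random pairs. Fcrls was seen in 92.5% (87.9 to 95.7%), above the 80% set beforehand. But 9 of 12 macrophage-like cluster 8 cells (42.8 to 94.5%) also had it, so that limit was wrong and the share does not separate the types. The Fcrls level did differ, at 2484 CPM (2407 to 2563) in injured cluster 3 and 965 CPM (719 to 1269) in injured cluster 8 cells. At least 2 UMIs of 10 microglia markers were found in 96.5% (92.9 to 98.6%), against 66.7% (34.9 to 90.1%) in cluster 8. The intervals do not overlap, so cluster 3 was not made up wholly of cells like cluster 8. The test cannot bound a mixture, because most cluster 8 cells also passed and their upper limit lay close to the cluster 3 interval. The sort for tdTomato 4 weeks after tamoxifen, which leaves circulating monocytes mostly unlabelled, makes blood-derived macrophages less likely by design. But tdTomato counts were not analysed, and 7 injured barcodes with endothelial or oligodendrocyte precursor markers passed the sort, so its purity is not known. Injured cluster 3 cells had 1 UMI of Ccr2, against 12 in the 13 injured cluster 8 cells. S100a6 and Ahnak stood at 21.5 and 5.68 CPM, against 397 and 284 CPM in injured cluster 8 cells. Ly6c2, Plac8 and Chil3 had at most 2 UMIs in either cluster. But Tgfbi was higher than in injured cluster 2 cells (92.8 against 34.8 CPM), and Fn1 was a leading gene. Macrophage genes were also higher than in cluster 2 (Ms4a7 78.9 against 10.7 CPM, Pf4 48.0 against 2.68 CPM). Blood-derived macrophages as a part of the cluster, macrophages unlike cluster 8 and a state of microglia after injury therefore stay open.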
